A study of Mus musculus with 83 samples.

How the data were processed

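RNA-seq libraries were made from 83 pools of laser-captured cortical neurons with a stranded total RNA kit for picogram input. The table deposited by the authors holds raw counts per Ensembl gene, which are not normalized. Alignment was with HISAT2 to GRCm38, per the submitters' processing notes. The counting tool, the annotation release and the strand setting are not given in the sources used here, so values of overlapping or antisense genes and of near-identical copies are uncertain. Of 48795 genes, 48349 matched a symbol and 446 did not, and coordinates are from GENCODE release M21. No molecular identifiers are given, so counting error is a lower limit of the error. No libraries held identical values.

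Libraries were grouped by neuron type and age from the labels. Library numbers within a group follow the order of the samples and pair nothing. The series gives 12 old and 9 young mice, and no group has more libraries than that, so each library within a type was taken as a separate mouse. The labels do not tie a library to a mouse and name no batch.

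Age was tested within each type with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust estimation, TMM factors and filterByExpr with a minimum count of 10, 2-sided, with Benjamini-Hochberg adjustment. Enrichment of a type against the mean of the other types, and the interaction of age and type, used a fit of all 8 groups. Fold changes are log2, old against young, with standard errors taken from the F statistic. CPM is relative to the library total, and M stands for mega. The design fixed 38 gene lists of cell markers, pathways and complexes, tested by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a correlation of 0.01, adjusted within each type. Lists with under 5 tested genes were not tested. Counts of positive and negative members use edgeR fold changes, and list medians use limma's. Library measures and list scores were compared by 2-sided exact permutation tests over all 293930 splits (12 against 9 libraries) or 125970 splits (12 against 8). Shared genes were tested with Fisher's exact test.

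Tests, lists and the rule for naming genes were set before the data were examined. For age, the 12 largest rises and falls among called genes at or above the median abundance were to be named, and where fewer passed, up to 5 per direction with the smallest unadjusted p under 0.01 were given as values that did not pass. Genes named by a Gm number, a Rik clone or a pseudogene suffix were passed over. Under the same rule, for the interaction the 12 genes with the smallest p, for enrichment the 8 largest folds per type and for lists up to 4 members with the smallest p were eligible, with a fixed panel of marker genes.

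Other settings tried were RLE size factors, no filter, a filter on CPM (at least 1 in 6 libraries and a mean of 2), DESeq2 1.42.0, limma-voom with quality weights, a fit of all groups, the library total, the F number in the titles (which the labels do not explain) and a surrogate variable (sva 3.50.0) as covariates, leaving out each library, young or old libraries alone for enrichment, and for lists an estimated correlation and fry. Chosen after seeing the data were leaving out or modelling the 6 libraries with under 3% mitochondrial counts, leaving out old VIP libraries with over 300 CPM of Sst, leaving out each library in the list tests, the list scores, and restricting the fit of all groups to genes at or above the median abundance. The tests were tried on simulated counts in which 100 genes were changed 2-fold and 100 4-fold for each comparison, and for age the ribosomal protein genes were also raised. Age fits made 3, 3, 1 and 1 false calls and the fit of all groups made 350 for the interaction and 236 for PYC enrichment.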

Results

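Gene expression was measured in pools of 125 neurons that were cut by laser from 14 µm sections of the frontal cortex of male C57BL/6 mice. Mice were young (2 months) or old (22 months). Pyramidal cells (PYC) and parvalbumin (PV), somatostatin (SST) and vasoactive intestinal peptide (VIP) interneurons were recognised by staining for Slc17a7, Pvalb, Sst and Vip. Each of the 4 types had 12 old libraries. PYC, SST and VIP had 9 young libraries each and PV had 8, for 83 libraries in all. Library totals ran from 1.46 to 27.2 M counts with a median of 6.99 M, and 11809 to 18248 genes had a count in a library. In 6 libraries the mitochondrially encoded genes, ribosomal RNA included, took 0.215% to 2.51% of counts, against 8.31% to 17.0% in the other 77.

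The first comparison asked what each captured pool held. The staining targets are given first, as a check on the capture, since the cells were picked by them. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, averaged 777 ± 225 CPM (SD, n = 12) in old and 880.3 ± 341 CPM (SD, n = 9) in young PYC pools. It was also present in interneuron pools, with 272 ± 83.9 CPM (SD, n = 12) in old PV, 322 ± 53.5 CPM (SD, n = 12) in old SST and 489.7 ± 122 CPM (SD, n = 12) in old VIP pools. Gad1, which encodes a GABA-synthesising enzyme, averaged 1760.4 ± 317 CPM (SD, n = 12) in old PV pools and 41.4 ± 22.3 CPM (SD, n = 12) in old PYC pools. Sst averaged 789 ± 199 CPM (SD, n = 12) in old and 843 ± 203 CPM (SD, n = 9) in young SST pools, Vip averaged 548 ± 203 CPM (SD, n = 12) in old and 871 ± 663 CPM (SD, n = 9) in young VIP pools, and Pvalb averaged 73.6 ± 32.5 CPM (SD, n = 12) in old and 80.8 ± 39.4 CPM (SD, n = 8) in young PV pools.

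**Figure D1:**
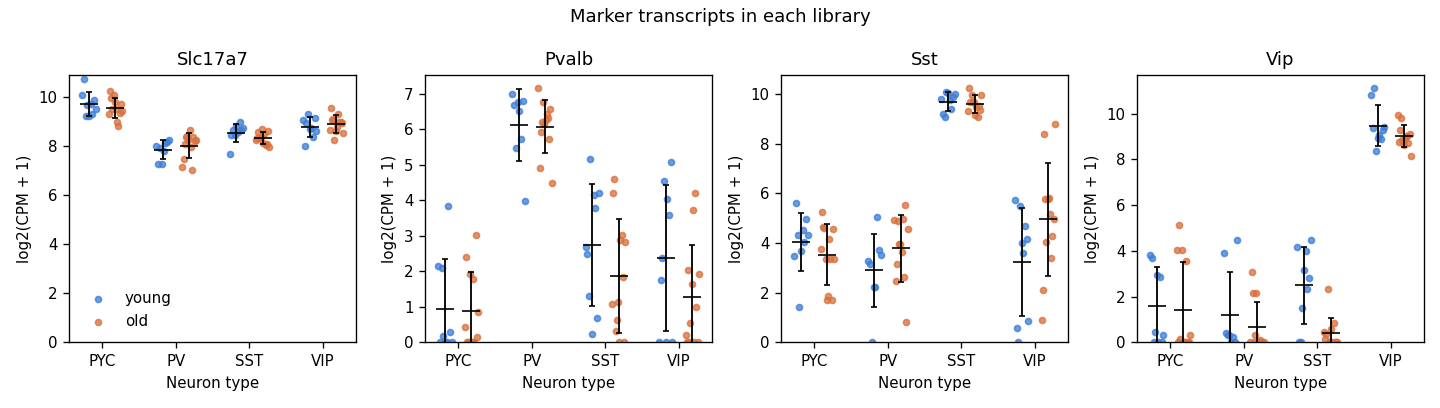
Transcript levels of Slc17a7, Pvalb, Sst and Vip in each library, as log2(CPM + 1) on the y axis, with the neuron type on the x axis. Blue points are young and orange points old libraries, bars give the mean ± SD of each group, and each target is highest in the type it was used to pick while Slc17a7 is present in all types.

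Genes that were not used for picking also separated the types. PYC pools were enriched in Fezf2, a transcription factor of deep-layer projection neurons, with a log2 fold change of 2.20 ± 0.39 (SE) against the mean of the other types (chromosome 14, 12342094 to 12348189, GRCm38). Scube1 (2.64 ± 0.23), the metabotropic glutamate receptor gene Grm2 (2.33 ± 0.33) and the somatostatin receptor gene Sstr3 (2.24 ± 0.43) were higher in PYC as well. PV pools were enriched in the potassium channel subunit gene Kcng4 (5.78 ± 0.69), the synaptotagmin gene Syt2 (5.12 ± 0.34), the perineuronal net gene Acan (4.55 ± 0.62) and the tachykinin precursor gene Tac1 (4.23 ± 0.62). SST pools were enriched in the opioid precursor gene Pdyn (4.93 ± 0.61), Reln (4.32 ± 0.29), the glutamate receptor subunit gene Grin3a (3.78 ± 0.24) and the neuropeptide gene Npy (3.75 ± 0.34). VIP pools were enriched in Grpr (8.26 ± 0.67), the serotonin receptor subunit gene Htr3a (7.70 ± 0.67), Npy2r (7.27 ± 0.63), Adarb2 (6.40 ± 0.43), the peptide gene Crh (6.31 ± 0.40), Tac2 (6.09 ± 0.60) and the transcription factor gene Prox1 (5.46 ± 0.46). All of these passed an edgeR adjusted p of 0.05.

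Marker lists were counted in the same way. The PV, SST, VIP and pyramidal lists hold the stained targets, whose result was built in by the capture. Every tested member of the PV list (15 of 15), the SST list (16 of 16) and the VIP list (17 of 17) was higher in its own pools, both over all genes and adjusted over the list alone. Lhx6, Sox6 and Satb1 are in both the PV and the SST list. Of PV markers 5 were also higher in SST pools and 1 was lower. Of SST markers 5 were higher and 9 lower in PV pools, and of VIP markers 6 were higher and 4 lower in SST pools. Of 21 pyramidal markers, 16 were higher in PYC over all genes and 19 adjusted over the list alone, and Cux2, an upper-layer gene, was lower. All 12 tested pan-GABAergic markers were lower in PYC, by both counts. VIP pools were also higher in 4 of the 21 pyramidal markers, Camk2a, Baiap2, Lamp5 and Cux2, and lower in 1, Slc30a3. The other 16 were not called in VIP. Few glial markers passed in any type. Of 16 astrocyte markers, 3 were lower in PV (Apoe, Slc1a2 and Clu), 2 were higher in VIP (Apoe and Glul), Slc1a2 was higher in PYC, and in SST Clu was higher and Aldoc lower.

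At an adjusted p under 0.05 and a log2 fold change of at least 1, edgeR called 975, 951, 800 and 1180 genes enriched in PYC, PV, SST and VIP among 19208 tested. On counts simulated with no difference the same fit made 141, 134, 173 and 143 calls in 18227 genes. Among genes at or above the median abundance, adjusted on their own, it called 285, 432, 200 and 246, and 0 in the simulation. Pools of different types must in part come from the same mice, which the labels do not record, so the fit could not be blocked on mouse and its p-values treat such pools as independent.

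The second comparison asked which genes differed between old and young mice within each type. No gene passed an adjusted p of 0.05 with edgeR fitted within any type, among 12508, 12564, 12805 and 12337 genes tested in PYC, PV, SST and VIP. At an unadjusted p under 0.05 there were 364, 291, 368 and 368 genes, or 2.91%, 2.32%, 2.87% and 2.98% of those tested. All of these shares were under the nominal level of 0.05, so the test was conservative here. With age labels shuffled within a type the median count was 295, 302, 299 and 243. As many genes as with the real labels were given by 19, 64, 8 and 6 of 100 splits, the real one included. Chance cannot be excluded for these counts. DESeq2 called 0, 2, 1 and 0 genes, which were Pkmyt1 and 1110065P20Rik in PV and Gm44950 in SST. Limma-voom with quality weights called 2, 2, 0 and 0, which were mt-Rnr1 and Gm23935 in PYC and Gm23935 and Gm24270 in PV. Of these, mt-Rnr1 encodes mitochondrial ribosomal RNA. The percentage of counts in ribosomal RNA-like genes differed by -1.83 between old and young PV pools (exact permutation p = 0.0228, adjusted p = 0.238). In PYC it differed by 0.0745 (exact permutation p = 0.968, adjusted p = 0.985). Whether the share of ribosomal RNA gave these limma-voom calls was not tested. The edgeR fit of all groups called 13, 1, 0 and 0 of 19208 genes, among them Rerg, Grpr, Crh and Gjd2 in PYC and Gm24447 in PV. Of these calls, 1 in PYC and 1 in PV were among the genes tested within the type. The genes called by these other tests were named after their values were seen. On simulated counts, edgeR recovered 15%, 16%, 16% and 5% of genes changed 2-fold and 40%, 39%, 34% and 22% of genes changed 4-fold. Among those at or above the median abundance of the changed genes it recovered 35.7%, 39.0%, 34.0% and 10.9% at 2-fold and 70.6%, 69.2%, 70.2% and 47.8% at 4-fold.

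In PYC pools the named genes are given as values that did not pass. Egr1, a transcription factor gene induced by neuronal activity (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, GRCm38), averaged 136 ± 47.3 CPM (SD, n = 12) in old and 253 ± 141 CPM (SD, n = 9) in young pools, a log2 fold change of -0.90 ± 0.24 (SE). Other negative values were -0.65 ± 0.19 for the active-zone gene Rimbp2, -0.60 ± 0.19 for the phosphodiesterase gene Pde10a, -0.97 ± 0.31 for Rtl1 and -0.71 ± 0.24 for Lmbrd1. Positive values were 1.25 ± 0.34 for the diacylglycerol kinase gene Dgkg, 1.53 ± 0.47 for the relaxin receptor gene Rxfp1, 0.43 ± 0.13 for the exchange factor gene Rasgrf1, 0.60 ± 0.17 for the translation elongation factor gene Eef1a1 and 1.66 ± 0.45 for Mir6236. Eef1a1 has near-identical copies elsewhere in the genome, and how reads shared with them were counted is not given in the sources used here.

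In PV pools, Calb1, which encodes a calcium-binding protein, averaged 60.9 ± 76.9 CPM (SD, n = 12) in old and 8.73 ± 11.5 CPM (SD, n = 8) in young pools, a log2 fold change of 2.75 ± 0.82 (SE) that did not pass. Other positive values were 1.05 ± 0.32 for Ildr2, 0.45 ± 0.13 for the adhesion receptor gene Adgrb3, 0.65 ± 0.21 for Tpt1 and 0.55 ± 0.18 for Tro. Negative values were -0.75 ± 0.21 for Trnp1, -1.14 ± 0.32 for the nuclear pore gene Nup153, -0.39 ± 0.11 for Ndrg3, -0.45 ± 0.13 for Arhgap35 and -0.80 ± 0.25 for the chaperonin subunit gene Cct8. Oligodendrocyte precursor markers summed to 65.6 ± 20.8 CPM (SD, n = 12) in old and 113 ± 44.2 CPM (SD, n = 8) in young PV pools, with an exact 2-sided permutation p of 0.00333 and an adjusted p of 0.0667 over 60 tests of library quality and marker sums, of which none had an adjusted p under 0.05.

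In SST pools, Camk2b, a subunit gene of calcium/calmodulin-dependent kinase, averaged 346 ± 58.5 CPM (SD, n = 12) in old and 475 ± 96.5 CPM (SD, n = 9) in young pools, a log2 fold change of -0.45 ± 0.13 (SE) that did not pass. Other negative values were -0.95 ± 0.28 for the mitochondrial glutamate carrier gene Slc25a22, -0.56 ± 0.17 for the mitochondrial import gene Tomm20, -0.86 ± 0.27 for Gnb2 and -0.64 ± 0.20 for the postsynaptic scaffold gene Dlgap4. Positive values were 0.89 ± 0.26 for the translation initiation factor gene Eif5b, 0.96 ± 0.28 for Cpeb2, 1.51 ± 0.44 for Fam78b, 1.86 ± 0.54 for AI597479 and 0.49 ± 0.15 for mt-Co3.

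In VIP pools, Skp1a, a ubiquitin ligase component gene, averaged 199.6 ± 65.9 CPM (SD, n = 12) in old and 107 ± 32.2 CPM (SD, n = 9) in young pools, a log2 fold change of 0.95 ± 0.23 (SE) that did not pass. Other positive values were 1.15 ± 0.34 for Ubxn7, 0.72 ± 0.23 for Ralgapa1 and 1.59 ± 0.42 for Vcp-rs, which is annotated as a processed pseudogene. Negative values were -0.66 ± 0.20 for Asap1, -0.78 ± 0.25 for the calcineurin subunit gene Ppp3cb, -0.56 ± 0.18 for Epb41l1, -0.72 ± 0.23 for Rbm25 and -0.46 ± 0.15 for the plasma membrane calcium pump gene Atp2b2. Vip itself was at -0.61 ± 0.29, and at 0.0012 without the VIP libraries with few mitochondrial counts. The other stained targets had log2 fold changes of -0.17 ± 0.18 for Slc17a7 in PYC, -0.17 ± 0.32 for Pvalb in PV and -0.09 ± 0.14 for Sst in SST pools, and none of these passed. The value for Slc17a7 was 0.07 with the F number of the titles as a factor, and that for Sst was 0.0051 with the library total as a covariate.

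Gene lists were compared between the ages with camera at a preset correlation, and 8 of 143 tests in the 4 types had an adjusted p under 0.05, while the other 135 did not. With an estimated correlation 0 passed, and with fry, which tests a list against no change and not against other genes, 0 passed, against 23 at an unadjusted camera p under 0.05. Immediate early genes, which neurons transcribe soon after activity, were lower in old SST pools, with 20 of 23 tested members negative and a median log2 fold change of -0.81 (camera adjusted p = 0.000462, and adjusted p = 0.107 with an estimated correlation). They were also lower in old PYC pools, with 17 of 22 negative and a median of -0.42 (camera adjusted p = 0.00532, and adjusted p = 0.108 with an estimated correlation). Single members had values of -0.73 ± 0.36 for Arc, -0.53 ± 0.29 for Egr1 and -1.41 ± 0.80 for Nr4a3 in SST, and -0.76 ± 0.27 for Arc and -0.81 ± 0.37 for Ier5 in PYC. No member passed over all genes in either type. Adjusted over the list alone, 1 member passed in PYC (Egr1, edgeR adjusted p = 0.0124) and 0 in SST.

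A score per library, the mean log2 CPM of the immediate early genes minus that of all tested genes, was -1.30 ± 0.447 (SD) in old and -0.520 ± 0.602 (SD) in young SST pools. All 12 old SST libraries lay below the young mean, with an exact permutation p of 0.00143 and an adjusted p of 0.205 over 143 scores. In PYC the score was 0.376 ± 0.359 (SD) in old and 0.834 ± 0.491 (SD) in young pools, with 11 of 12 old libraries below the young mean, an exact permutation p of 0.0150 and an adjusted p of 0.537. In the same SST pools, lists of pyramidal markers (11 of 18 negative, camera p = 0.0273, adjusted p = 0.141) and PV markers (9 of 12 negative, camera p = 0.305, adjusted p = 0.732) did not pass. Their scores differed by -0.249 (exact permutation p = 0.107) and -0.391 (exact permutation p = 0.0471) between old and young, with adjusted p of 0.806 and 0.749, and Slc17a7 was at -0.25 ± 0.14. Without young PYC replicate 2, a library with few mitochondrial counts, the PYC list did not pass (camera adjusted p = 0.0534). In PV 13 of 20 members were negative with a median of -0.52. In VIP 13 of 24 were negative by edgeR, but limma gave a positive median of 0.23 and mean of 0.23, and the score was higher in old pools by 0.0975. Neither list passed (camera adjusted p = 0.0667 and 0.988). The difference of the list between types was not tested.

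**Figure D2:**
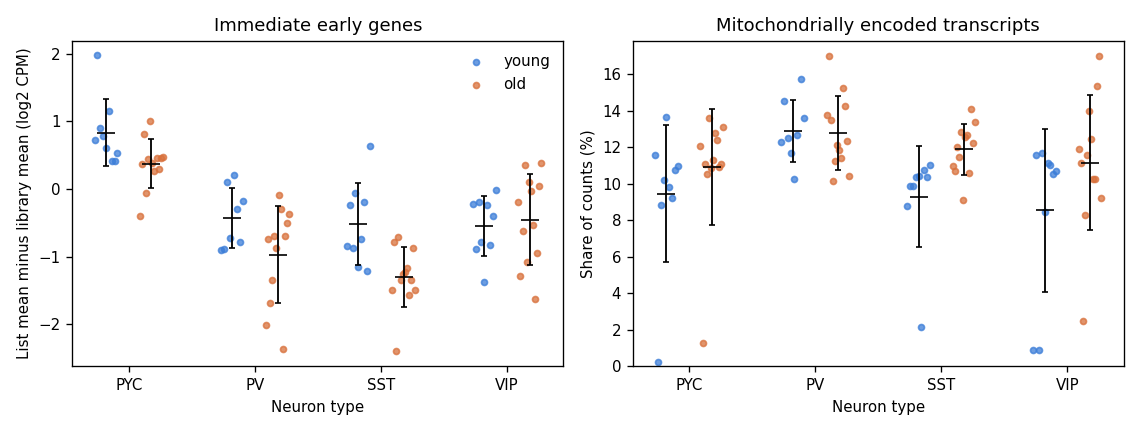
Left, the immediate early gene score of each library (mean log2 CPM of the list minus that of all tested genes). Right, the percentage of counts in mitochondrially encoded genes, ribosomal RNA included. Both panels have the neuron type on the x axis. Blue points are young and orange points old libraries, bars give the mean ± SD, and 6 libraries lie at 2.51% or less in the right panel.

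Mitochondrially encoded genes were higher in old SST pools, with 13 of 13 tested members positive and a median log2 fold change of 0.52 (camera adjusted p = 2.41e-14, and adjusted p = 0.165 with an estimated correlation). Adjusted over the list alone 3 passed, mt-Co3 at 0.49 ± 0.15, mt-Co2 at 0.51 ± 0.17 and mt-Co1 at 0.36 ± 0.13, and 0 passed over all genes. All mitochondrial transcripts, ribosomal RNA included, took 11.9 ± 1.38% (SD, n = 12) of counts in old and 9.29 ± 2.76% (SD, n = 9) in young SST pools. This difference had an exact permutation p of 0.00137 and an adjusted p of 0.0667. Mitochondrial ribosomal RNA, which is not in the list, made up most of it, at 10.6 ± 1.34% (SD) in old and 8.29 ± 2.51% (SD) in young pools. Young SST replicate 6 was at 2.14% for all mitochondrial transcripts. Without it the old minus young difference of the list's score went from 0.513 (exact permutation p = 0.0375) to 0.242 (exact permutation p = 0.121). The list stayed called (camera adjusted p = 6.96e-07). A camera call alone says little for this list, as shuffled age labels among SST libraries gave it a median camera p of 0.000252. The score did not pass over 143 scores with all libraries (adjusted p = 0.670). In old VIP pools 13 of 13 members were positive with a median of 0.65 (camera adjusted p = 5.42e-06, and adjusted p = 0.595 with an estimated correlation). This call ended without young VIP replicate 3 (camera adjusted p = 0.0569) and without all VIP libraries with few mitochondrial counts (camera adjusted p = 0.566).

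Cytosolic ribosomal protein genes were higher in old PYC pools, with 61 of 80 positive, a median log2 fold change of 0.20 and Rpl28 at 0.79 ± 0.35 (camera adjusted p = 0.0304, and adjusted p = 0.734 with an estimated correlation). They were lower in old SST pools, with 53 of 79 negative, a median of -0.24 and Rpl8 at -0.71 ± 0.23 (camera adjusted p = 0.00822, and adjusted p = 0.165 with an estimated correlation). Nuclear genes of oxidative phosphorylation were higher in old PYC pools, with 51 of 77 positive, a median of 0.18 and the complex I subunit gene Ndufs4 at 1.0 ± 0.31 (camera adjusted p = 0.0409, and adjusted p = 0.734 with an estimated correlation). Developmental and neurogenesis genes were lower in old VIP pools, with 13 of 17 negative, a median of -0.22 and Stmn2 at -0.62 ± 0.24 (camera adjusted p = 0.0317, and adjusted p = 0.595 with an estimated correlation). In the same VIP pools, lists of SST markers (11 of 13 positive, camera p = 0.0111, adjusted p = 0.130) and of oligodendrocyte and myelin markers (11 of 15 negative, camera p = 0.0169, adjusted p = 0.147) did not pass. Nor did VIP markers (camera direction down, camera p = 0.0393, adjusted p = 0.197, median 0.03), and Sst was at 2.29 ± 1.04, with 439 and 331 CPM in old VIP replicates 9 and 11. No member of the ribosomal protein, oxidative phosphorylation or developmental lists passed over all genes or adjusted over the list alone. Leaving out 1 library ended the ribosomal protein call for 5 of 21 libraries in PYC (adjusted p = 0.00336 to 0.155) and 2 in SST (0.00224 to 0.0631), the oxidative phosphorylation call for 11 (0.00502 to 0.201) and the developmental call for 9 (0.00861 to 0.111). Many ribosomal protein genes have pseudogene copies that share reads. The median library total was 6.13 M in old and 9.75 M in young SST pools.

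The third comparison asked whether age acted differently between the types. The edgeR test of the interaction over all 8 groups called 601 of 19208 genes, and 549 of the called genes had a group without a single count. On counts simulated with no difference it called 311 of 18227 genes. Among genes at or above the median abundance, adjusted on their own, it called 1, Crh, a stress peptide gene. Crh averaged 0.0147 ± 0.0508 CPM in old and 1.18 ± 1.53 CPM in young PYC pools (SD), against 72.5 ± 54.5 and 104 ± 48.4 CPM in VIP pools. It had a count in 1 old and 7 young PYC libraries (edgeR adjusted p = 0.00251 over all genes), and it did not pass with limma-voom (adjusted p = 0.529). Skp1a had log2 fold changes of 0.95 ± 0.20 (SE) in VIP and 0.09 ± 0.19 in PYC (edgeR adjusted p = 0.0116 over all genes), and Ildr2 of 1.05 ± 0.24 in PV and -0.22 ± 0.22 in PYC (edgeR adjusted p = 0.0249 over all genes). Neither passed among the abundant genes alone (adjusted p = 0.221 and 0.416) or with DESeq2 (adjusted p = 0.241 and 0.269).

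The last comparison asked whether age differences were shared between types. With no called gene in any type, 0 calls were shared. At an unadjusted p under 0.01, 3 genes were shared in direction, all between PYC and VIP. Of these, 2 were negative in both, against 0.0510 expected for lists of 21 and 28 genes (1-sided Fisher's exact test p = 0.00116, adjusted p = 0.0139 over 12 tests), and 1 was positive in both (p = 0.0845, adjusted p = 0.507). Over genes, which are not independent replicates, Spearman's rho of the log2 fold changes was 0.0789 between PYC and VIP and ran from -0.0269 to 0.0351 for the other pairs. Over the 5208 genes at or above the median abundance in both PYC and VIP it was 0.158, and it ran from -0.0198 to 0.0498 for the other pairs. The labels do not record which pools of different types came from the same mouse, and shared mice can make age differences of types alike. Fisher's test takes the genes and the types as independent, so its p is too small where they are not. The overlap and the correlation were not repeated without the libraries with few mitochondrial counts, which PYC and VIP both hold. Within each age, those libraries of PYC and VIP carry the same F number in their titles. Neither the overlap nor the correlation was repeated with the F number as a factor.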

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

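The tests of the immediate early genes against library depth and low mitochondrial shares, and that of the interaction genes against groups without counts, were chosen after the results were seen. Of 71 groups of measures tested for a library far from the rest, 5 held one, and chance gives about 5%. Only young groups were tested, because the limits used did not cover groups as large as the old ones. Old libraries were not screened in this way. Of these, old PYC replicate 10 (1.26%) and old VIP replicate 11 (2.51%) also had a low mitochondrial share. Young PYC replicate 2 had a mitochondrial share of 0.215% against 8.84% in the nearest library, and an immediate early gene score of 1.98 against 1.16. Young SST replicate 6 had a total of 27.2 M counts against 11.4 M, a mitochondrial share of 2.14% against 8.75%, and a score of mitochondrially encoded genes of 2.26 against 4.25.

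Immediate early genes were lower in old PYC and SST pools, by a mean score difference of -0.621 ± 0.147 (SE, which here and below takes PYC and SST pools as independent, though they can come from the same mice). Without the libraries with few mitochondrial counts the difference was -0.563 ± 0.143, and with the library total as a covariate it was -0.551 ± 0.157, so the tables argue against either as the whole cause. In PYC alone the call ended without those libraries, where the score difference went from -0.457 to -0.314 (exact permutation p = 0.0562). A difference in handling or in batch between the ages, which the labels do not record, a difference in the cells of the pools, with SST pools at -0.249 for the pyramidal and -0.391 for the PV marker score, and age itself stay open and were not tested. The lists' tests with an estimated correlation did not pass, and the number of called lists in PYC and in SST was within chance, so a lower activity-related transcription in old mice is a hypothesis only.

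The age difference differed between types, by the edgeR interaction test, for 12 named genes, with adjusted p-values of 0.00251 for Crh, 0.010 for Dnah9, 0.0116 for Skp1a, 0.0126 for Htr3a, 0.0139 for Grpr, 0.0170 for Gjd2, 0.0198 for Lgals1, 0.0249 for Snx8, 0.0249 for Ildr2, 0.0312 for Eef1a1, 0.0322 for Rerg and 0.0340 for Ndrg3. Over all 601 called genes, 91.3% had a group without counts, against 11.7% of tested genes, as an excess of false calls at low counts would give. With ages permuted within each type, 45 of 60 splits called as many genes, with a median of 631 and a highest of 804, so chance cannot be excluded for the count. Among the named genes, Htr3a, Grpr and Lgals1 had a group without counts. Crh, Dnah9, Gjd2, Snx8 and Rerg had counts in every group but very few in some. Rerg had a count in 1 old and 3 young PYC libraries, and Dnah9 averaged 0.244 CPM in young PV pools. For Skp1a, Ildr2, Eef1a1 and Ndrg3, which had counts in every library, a group without counts is not the reason for the call. Their adjusted p among abundant genes alone was 0.221, 0.416, 0.540 and 0.540, the highest over their alternatives was 0.299, 0.416, 0.828 and 0.829, and a biological difference between the types stays open.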

How the results depend on the processing

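Alternatives leaving out or modelling the libraries with few mitochondrial counts or the old VIP libraries with the most Sst, list scores, leaving out libraries in the list tests and abundant genes alone were chosen after seeing the data. No paired analysis was possible because the labels do not tie libraries to mice. The count of age-related genes stayed at 0 in every type with RLE factors, the CPM filter, the library total, the F number, and a surrogate variable, and in PYC, SST and VIP, which hold the low mitochondrial libraries, without these or with them as a covariate. In VIP it was also 0 without old replicates 9 and 11, which had the most Sst. It was 0 to 0 when each library was left out. The CPM filter kept more genes than the edgeR one (14257, 13667, 14454 and 14530 in PYC, PV, SST and VIP). With no filter it was 6505, 6355, 5734 and 7117, of which 92, 69, 75 and 107 were among the genes of the filtered test. DESeq2 gave 2 in PV and 1 in SST, limma-voom 2 in PYC and 2 in PV, and a fit of all groups 13 in PYC and 1 in PV; the cause was not tested. Signs of named genes were not checked when single libraries were left out. In the other settings, of 40 age genes named by rule, 0 changed sign. Those genes were picked by small p in the same data, so a kept sign is no independent support. Of 43 values of the fixed panel 15 changed sign, none of which had passed. Among these is Vip in VIP, at -0.61, which was 0.0012 without low mitochondrial libraries; the cause was not tested. Shared age-related genes went from 0 to 3 at an unadjusted p under 0.01, where more genes enter.

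The adjusted p of the called lists is given in the order oxidative phosphorylation, ribosomal protein and immediate early genes in PYC, mitochondrially encoded, ribosomal protein and immediate early genes in SST, and mitochondrially encoded and developmental genes in VIP. It was 0.734, 0.734, 0.108, 0.165, 0.165, 0.107, 0.595 and 0.595 with an estimated correlation, 0.779, 0.779, 0.130, 0.248, 0.0982, 0.0641, 0.497 and 0.457 with fry and 0.806, 0.806, 0.537, 0.670, 0.590, 0.205, 0.936 and 0.410 with list scores per library. Of 8 lists, 0 passed with an estimated correlation and 0 with list scores. Fry asks another question, whether a list's genes move against no change and not against other genes, and 0 passed there. Without low mitochondrial libraries 4 lists were called, and oxidative phosphorylation (0.161) and immediate early genes (0.0643) in PYC and mitochondrially encoded (0.566) and developmental genes (0.398) in VIP were lost. Oxidative phosphorylation in PYC was also lost with RLE factors (0.0516) and the library total (0.242), and developmental genes in VIP with the CPM filter (0.0778) and the library total (0.0947); the cause was not tested.

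Leaving out each library gave an adjusted p of 0.00502 to 0.201 for oxidative phosphorylation, 0.00336 to 0.155 for ribosomal protein and 0.000797 to 0.0534 for immediate early genes in PYC, 3.23e-18 to 6.96e-07 for mitochondrially encoded, 0.00224 to 0.0631 for ribosomal protein and 4.26e-05 to 0.0131 for immediate early genes in SST, and 3.25e-10 to 0.0569 for mitochondrially encoded and 0.00861 to 0.111 for developmental genes in VIP. Removal of these libraries ended a call, with the adjusted p without each. For oxidative phosphorylation in PYC these were old replicates 2 (0.0626), 3 (0.0653), 4 (0.0853), 8 (0.114), 9 (0.0572) and 11 (0.127) and young replicates 2 (0.201), 3 (0.102), 5 (0.0800), 7 (0.118) and 8 (0.117). For ribosomal protein genes in PYC they were old replicates 4 (0.107) and 8 (0.0622) and young replicates 3 (0.0708), 7 (0.155) and 8 (0.154), and for immediate early genes young replicate 2 (0.0534). In SST they were old replicate 6 (0.0594) and young replicate 9 (0.0631) for ribosomal protein genes. In VIP they were young replicate 3 (0.0569) for mitochondrially encoded genes, and old replicates 1 (0.0571), 6 (0.0801), 8 (0.0595) and 10 (0.0969) and young replicates 1 (0.0715), 2 (0.111), 3 (0.0569), 4 (0.0556) and 9 (0.0588) for developmental genes; the cause was not tested.

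The interaction count of 601 was 8 with the CPM filter, 1 with DESeq2, 8 with limma-voom, 315 with the F number and 1 among abundant genes. For the named interaction genes, 57 values over all settings did not pass and 39 did; the cause was not tested. Enriched genes in PYC, PV, SST and VIP numbered 270, 371, 172 and 301 in young and 259, 371, 170 and 220 in old libraries alone, where fewer libraries were used, 285, 432, 200 and 246 among abundant genes, where fewer genes were tested, and 593, 649, 499 and 732 with DESeq2. Named enriched genes kept their direction in these settings and passed, except, in old libraries alone, Ltk enriched in PYC (adjusted p = 0.0851) and Lgals1 enriched in SST (adjusted p = 0.0938). The named enriched genes were picked by fold in the same data, so this is no independent support. What depth limits was not tested, as the simulated counts held 1 depth and 1 number of libraries.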

Other observations

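The immediate early gene score over all types was chosen after the results were seen. VIP pools held transcripts usually ascribed to excitatory neurons. Camk2a, a kinase gene, averaged 2289 ± 447 CPM (SD) in VIP and 2118 ± 341 CPM (SD) in PYC pools. In PV and SST pools it averaged 1101 and 1375 CPM. Astrocyte markers summed to 3563 ± 413 CPM (SD, n = 12) in old VIP and 2377 ± 722 CPM (SD, n = 12) in old PV pools. Old VIP replicates 9 and 11 had 439 and 331 CPM of Sst, against a median of 32.4 CPM in their group. Calcium signalling genes in old SST pools had 28 of 36 negative members, 1 of which passed adjusted over the list alone, and the list did not pass (camera adjusted p = 0.102). Of 13 SST markers tested with age in PV pools, 1 was higher in old pools adjusted over the list alone, and that list did not pass either (camera adjusted p = 0.678).

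Among 400 pairs of libraries of a group the median Spearman correlation over genes was 0.725, and over the other pairs 0.685. The closest pair was young SST replicate 6 and old VIP replicate 11, at 0.873, and both have few mitochondrial counts (2.14% and 2.51%) and high totals (27.2 and 16.9 M). They shared 0 genes seen in exactly 2 libraries, where 1.40 were expected by chance.

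Other splits of the libraries were drawn with a fixed seed, the real split included. For the count of age-related genes, 100, 100, 100 and 100 of 100 splits in PYC, PV, SST and VIP gave as many as the real 0, as any split must, with a highest other count of 1, 1, 0 and 3. For enrichment, 1 of 60 splits gave as many in each type, the real one. The highest other count was 392, 322, 432 and 346, and the median other count 194, 194, 202 and 209. No shuffled split reached the real counts. The pools were picked by type, so a difference was built in by the capture. Shuffling also takes pools that share a mouse as independent. Of 100 splits, as small a camera p was given by 4 for oxidative phosphorylation, 6 for ribosomal protein and 3 for immediate early genes in PYC. In SST it was given by 1 for mitochondrially encoded, 2 for ribosomal protein and 1 for immediate early genes, and in VIP by 17 for mitochondrially encoded and 6 for developmental genes. The real and the smallest other p were, in that order, 0.00341 and 0.000809, 0.00169 and 0.000129, 0.000148 and 1.43e-05, 6.69e-16 and 1.75e-13, 0.000685 and 0.000142, 2.56e-05 and 0.00215, 1.55e-07 and 2.05e-18, 0.00181 and 7.22e-05. The median other camera p was 0.000252 in SST and 0.00377 in VIP for mitochondrially encoded genes. It ran from 0.216 to 0.349 for the other called lists. Camera thus gave mitochondrially encoded genes a small p for many shuffled splits. These lists were taken for the splits because camera had called them among 143 tests, so a low count for a list does not exclude chance. As many lists as the real 3, 0, 3 and 2 in PYC, PV, SST and VIP were called by 17, 100, 6 and 27 of 100 splits, with a highest other count of 7, 7, 6 and 7, so chance cannot be excluded for the number of called lists in PYC, SST or VIP. In PV the real count of 0 is reached by any split, which decides nothing. The mean Spearman correlation of age effects between types, 0.0177, was reached by 8 of 100 splits, with a highest other of 0.0319, so chance cannot be excluded for the mean. By pair, as high a correlation was given by 2 splits for PYC and VIP (real 0.0789, highest other 0.106), 5 for PYC and SST (real 0.0351, highest other 0.0698), 97 for PYC and PV, 21 for PV and SST, 55 for PV and VIP and 36 for SST and VIP, without adjustment for the number of pairs.

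The immediate early gene score averaged over the 4 types differed by -0.422 between old and young libraries (permutation p = 0.00114). Without low mitochondrial libraries it differed by -0.365 (permutation p = 0.00651). The p takes libraries as independent, but 83 libraries from 12 old and 9 young mice must share animals, so it counts the same mice several times. The average includes the PYC and SST differences that prompted it and is no independent evidence. By type the difference was -0.457, -0.543, -0.784 and 0.0975 in PYC, PV, SST and VIP, so VIP went the other way, and by 0.210 without its low mitochondrial libraries. Removing low mitochondrial libraries is no independent test for the mitochondrially encoded genes themselves, since the libraries were chosen by those counts.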
